A study of Mus musculus with 3 samples.

How the data were processed

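Single-cell RNA sequencing of mouse lung was available as 3 libraries, 1 per group: lung of a non-irradiated control, lung after thoracic irradiation in conventional mode (CONV) and lung after thoracic irradiation in FLASH mode, in which the dose is delivered at an ultra-high dose rate. Per the labels' protocols, C57BL/6 females of 10 to 12 weeks received 17 Gy of 4.5 MeV electrons under isoflurane. Lungs were dissociated enzymatically, passed through 100 and 40 µm filters, freed of red blood cells by lysis and loaded on the 10x Genomics 3' version of the Chromium system, with 26 cycles for read 1 and 98 for read 2. The number of mice per library and the time between irradiation and sampling were not given in the sources used here.

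The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell barcode, whole numbers with no normalization, which the authors made with Cell Ranger 2.0 on genome build mm10, per the submitters' processing notes. The matrices held 27998 genes and 6662 barcodes: 1761 in the control, 2507 in CONV and 2394 in FLASH. Gene positions were taken from GENCODE M21 on mm10, in which 27722 of the 27998 gene identifiers were found. The total was 7114360 UMIs in the control, 7463259 in CONV and 5498902 in FLASH, with medians of 2960, 2351 and 1776.5 UMIs and 1247, 1088 and 887 genes per barcode. FLASH was therefore the shallowest library per cell. The width of an interval follows the UMIs summed over a compartment. A count of 0 cells allowed a share of up to 0.176% of the control, 0.126% of CONV and 0.133% of FLASH cells, taking 3 counts as the limit.

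Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which removed 50 for few genes and 154 for mitochondrial share. Scrublet, as implemented in scanpy, was run per library, and the top-scoring share set by a loading rate of 0.8% per 1000 barcodes was removed as doublets, 121 in all. Its automatic threshold marked 44 barcodes (0.660%). The 6346 kept cells (1705 control, 2388 CONV, 2253 FLASH) were scaled to 10000 UMIs and log transformed. The 2000 most variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1, without integration of the libraries. Clusters were named from markers of 32 cell types, and a cluster needed at least 3 detected markers, detected in 10% of its cells and 2 times higher than elsewhere. These naming limits were set after the data had been seen. Names are based on markers only and are therefore read as "like" that type, and 4 clusters without a leading marker of their own stayed unnamed. Each cluster also belongs to a compartment (lymphoid, myeloid, epithelial, stromal or endothelial). Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.

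The 3 comparisons were CONV against control, FLASH against control and FLASH against CONV. With 1 library per group there was no replicate check and no test across animals, so no p-value is given. Shares of cells carry exact Clopper-Pearson intervals, and differences of shares Newcombe intervals. Gene levels are UMIs summed over the cells of a class or compartment, scaled by all UMIs of those cells and given in CPM, with exact Poisson intervals, and ratios carry exact conditional binomial intervals. All intervals are at 95% and cover counting error only, not the differences between animals, dissociations or loadings. Shares depend on dissociation and loading as well as on the tissue. A gene list is summarised by the median log2 ratio of its members with at least 10 UMIs, with a pseudocount of 1 CPM, and by its percentile among 10000 random lists of the same size and matched expression. The percentile describes these libraries and is not a test. Interval bounds of list medians come from 1000 Poisson draws.

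Cycling cells were those with at least 2 UMIs of the G2/M list after each cell was thinned to 1000 UMIs. The 10 shallower FLASH cells were left out, and none in the other libraries. The 16 gene lists covered p53 targets, S phase, G2/M phase, interferon-stimulated genes, inflammatory cytokines and NF-kB, extracellular matrix and TGF-beta, MHC class II, MHC class I, immediate early genes, surfactant, the Krt8-high transitional epithelium, endothelial activation, NRF2, senescence, mitochondrially encoded genes and haemoglobin. Groups, tests, lists, markers and the rule for named genes were fixed before the data were examined. By that rule, the 2 genes with the highest and the 2 with the lowest ratio were named for each comparison in the 6 largest classes, ranked by the bound of the interval nearest to 1. A gene needed at least 30 UMIs in the higher library and at least 10% of its level in the class where it was highest. Ribosomal, mitochondrial, haemoglobin, immunoglobulin and T cell receptor genes, Xist, Y-linked genes, predicted genes and markers of other classes were left out. Within a list, up to 4 members with the most UMIs were named, and Cdkn1a, Mki67, Top2a, Il1b, Tnf, Il6, Tgfb1, Cxcl1, Sftpc and Scgb1a1 always. A gene that the rule selected in alveolar macrophage-like cells and a gene of the thymocyte group are not reported here. Any other gene named was chosen after its values were seen. Of the listed genes 1, and of the markers 7, were not in the matrices. A narrow G2/M list, a group of thymocyte genes and a group of circadian clock genes were added after the clusters had been seen.

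The intervals and medians were tested on simulated data for CONV against control over all cells. Counts were drawn per gene from a Poisson distribution, which the intervals also assume, and no single cells were simulated. The test therefore checks the calculation only. It cannot show whether an interval is too narrow where the UMIs of a gene lie in a few cells. Of 11007 genes with no planted change, 4.60% of the intervals excluded 1, and 95.7% held the true ratio. At planted ratios of 4, 2, 0.5 and 0.25, with 50 genes each, 92%, 94%, 98% and 94% of the intervals held the true ratio, and 100%, 100%, 98% and 100% excluded 1. A list of 20 genes with a planted ratio of 2 had a median log2 ratio of 0.94, and an unchanged list one of -0.08. Another scaling, by the median ratio over genes with at least 50 UMIs, moved lymphoid cells by -0.18 (CONV) and -0.17 (FLASH) on the log2 scale against the control, and the other compartments by 0.09 or less in size.

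Other settings tried were mitochondrial limits of 5% and 20%, a minimum of 500 genes, no doublet removal or the automatic threshold, resolutions of 0.5 and 2, assignment of each cell by its own marker score, separate clustering of the libraries, cells thinned to 1000 UMIs, other limits for cycling cells, a mean over cells, median-ratio scaling, a pseudocount of 10 CPM, list members with 1 or 50 UMIs, and classes weighted equally. Alternatives without clusters of 1 library (at least 95% of cells from it), without clusters with at least 80% of cells from the control, among non-lymphoid cells, with a narrow G2/M list, with list members at 10% or more of their highest compartment, without Cdkn1a and with another random seed were added after seeing the data.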

Results

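The series profiles mouse lung by droplet single-cell RNA sequencing in 3 libraries: a non-irradiated control, 17 Gy of thoracic irradiation in conventional mode (CONV) and 17 Gy in FLASH mode. After filtering, 1705 control, 2388 CONV and 2253 FLASH cells formed 26 clusters. They included cells like alveolar type 2 (AT2), type 1, club and ciliated epithelium, capillary and lymphatic endothelium, fibroblasts, smooth muscle, mesothelium, macrophages, monocytes, dendritic cells, neutrophils and B, T and NK lymphocytes. Values in brackets after a share, ratio or median are 95% intervals for counting error only, and each group is 1 library (n = 1), so differences between libraries are described as higher or lower.

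Lymphoid cells made up most of the control suspension and a much smaller part of both irradiated ones. Their share was 58.6% (56.2 to 60.9) in the control, 21.2% (19.6 to 22.9) in CONV and 23.9% (22.1 to 25.7) in FLASH, a difference from the control of -37.4 points (-40.2 to -34.5) and -34.7 points (-37.6 to -31.7). Epithelial cells held 11.6% (10.1 to 13.2), 24.7% (23.0 to 26.5) and 22.4% (20.7 to 24.2), myeloid cells 13.6% (12.0 to 15.3), 25.8% (24.1 to 27.6) and 27.1% (25.2 to 29.0), and stromal cells 10.9% (9.41 to 12.4), 24.4% (22.7 to 26.1) and 21.6% (19.9 to 23.4). Endothelial cells held 5.34% (4.32 to 6.51), 3.89% (3.15 to 4.75) and 5.02% (4.15 to 6.00).

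B-like cells, the antibody lineage, were 13.5% of the control, 3.98% of CONV and 6.08% of FLASH cells, differences of -9.51 points (-11.4 to -7.75) and -7.41 points (-9.34 to -5.54). NK-like cells, innate cytotoxic lymphocytes, were 5.22%, 2.60% and 4.22%, with -2.62 points (-3.91 to -1.43) in CONV and -1.0 points (-2.39 to 0.319) in FLASH. T-like cells were 25.3%, 13.6% and 12.5%. Of the T-like and unnamed lymphoid cells in the control, 320 formed 2 clusters of 99 and 221 cells that held no cell of either irradiated library, and another T-like cluster of 198 cells was 82.3% control. These 3 control-rich clusters were marked by Rag1, Ccr9 and Endou, by Top2a and Birc5, and by Itm2a and Ikzf2. Without them T-like cells were 13.8%, 12.8% and 11.9%, with differences of -0.992 points (-3.41 to 1.31) and -1.94 points (-4.36 to 0.358), while the B-like share was 18.8%, 4.01% and 6.12%.

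AT2-like cells, the surfactant makers, were 7.92% of the control, 16.9% of CONV and 14.7% of FLASH cells, and ciliated-like cells 1.17%, 4.10% and 4.04%. Non-classical monocyte-like cells, which patrol vessels, were 3.64%, 9.34% and 9.76%, alveolar macrophage-like cells 4.11%, 8.25% and 8.97%, and alveolar fibroblast-like cells 4.28%, 10.0% and 8.79%. Neutrophil-like cells were 0.821%, 1.93% and 1.60%, interstitial macrophage-like cells 1.70%, 3.69% and 3.95%, and type 2 dendritic-like cells 3.05%, 2.14% and 1.78%. Within the non-lymphoid cells epithelium was 28.0%, 31.3% and 29.4%, and myeloid cells 32.9%, 32.8% and 35.6%, so most of their higher share over all cells reflects the lower lymphoid share. Endothelial cells were 12.9%, 4.94% and 6.59% of the non-lymphoid cells, a difference from the control of -7.95 points (-10.8 to -5.43) in CONV and -6.30 points (-9.18 to -3.70) in FLASH.

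**Figure D1:**
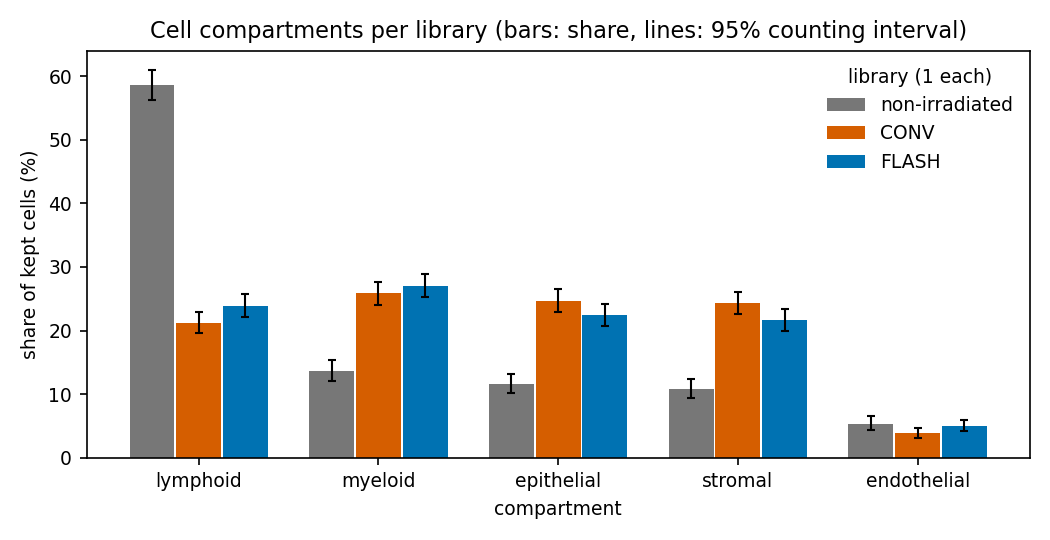
Share of kept cells (percent, vertical axis) in the 5 compartments for the control, CONV and FLASH libraries, with 95% Clopper-Pearson intervals as error bars. Lymphoid cells are 58.6%, 21.2% and 23.9%.

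Cells with G2/M transcripts, those near division, were 33.8% of the control (31.6 to 36.1; 577 of 1705), 12.9% of CONV (11.5 to 14.3; 307 of 2388) and 13.6% of FLASH cells (12.2 to 15.04; 304 of 2243). Without the 3 control-rich clusters the shares were 21.4%, 12.6% and 13.4%, so a difference of -8.77 points (-11.5 to -6.16) in CONV and -7.94 points (-10.7 to -5.28) in FLASH was left. The limit also passes cells that may not divide: 11.4% of control stromal cells did pass it, although 0 of 185 did so with a narrow list of mitotic genes. With the narrow list the shares without these clusters were 1.39% (0.812 to 2.22), 1.27% (0.856 to 1.80) and 0.718% (0.411 to 1.16). By compartment, 9 of 232 control and 27 of 617 CONV myeloid cells passed the narrow list, and 3 of 198 control but 0 of 590 CONV epithelial cells, a difference of -1.52 points (-4.36 to -0.325). In FLASH 1 of 505 epithelial cells passed, a difference of -1.32 points (-4.17 to 0.0372). Both epithelial differences rest on the 3 control cells. Carry-over from the dividing control-only cells is not excluded for them, since 14 of 706 non-lymphoid control cells held at least 2 UMIs of Rag1, Rag2, Dntt and Ptcra. Mki67, made in all dividing cells, was at 66.5, 9.8 and 7.9 CPM over all cells and at 11.7, 9.9 and 7.9 CPM without these clusters. Top2a, the topoisomerase that untangles chromosomes, was at 186, 13.1 and 9.6 CPM, and at 21.9, 13.2 and 9.5 CPM without them.

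**Figure D2:**
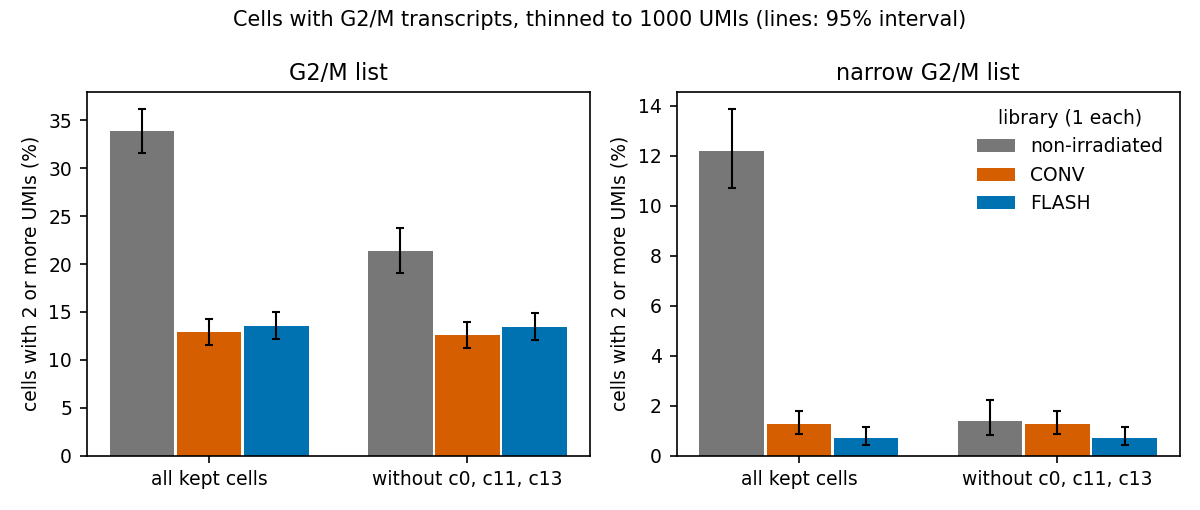
Share of cells (percent, vertical axis) with at least 2 UMIs of the G2/M list or of the narrow list after thinning to 1000 UMIs, for all kept cells and without the 3 control-rich clusters, with 95% Clopper-Pearson intervals as error bars. With the G2/M list all control, CONV and FLASH cells are at 33.8%, 12.9% and 13.6%.

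After CONV irradiation p53 targets were higher in every non-lymphoid compartment. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 124 CPM in control stromal cells and 699 CPM in CONV, a ratio of 5.63 (4.50 to 7.13). Its ratio was 3.17 (2.70 to 3.74) in epithelial, 2.36 (2.11 to 2.63) in myeloid and 2.19 (1.86 to 2.57) in endothelial cells, where its control level of 920 CPM was highest. In alveolar fibroblast-like cells it went from 43.6 to 677 CPM, 15.5 times the control (8.35 to 32.7). Ccng1, which encodes the p53-induced cyclin G1, was at 17.0 and 164 CPM in AT2-like cells, a ratio of 9.64 (5.74 to 17.5).

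The median log2 ratio of the p53 list was 1.21 (1.00 to 1.55) in endothelial cells with 14 of 19 members higher, 0.95 (0.79 to 1.15) in epithelial cells with 22 of 24, 0.92 (0.68 to 1.10) in stromal cells with 21 of 24, and 0.49 (0.36 to 0.81) in myeloid cells with 21 of 24. Each was at percentile 100 of the random lists. In lymphoid cells it was 0.07 (-0.28 to 0.28), and 0.50 (0.14 to 0.61) without the control-rich clusters. Rps27l, a ribosomal protein paralog under p53 control, had ratios of 2.81 in endothelial, 1.95 in epithelial and 1.86 in stromal cells. Phlda3, a p53-induced repressor of Akt, was 2.84 (2.15 to 3.78) in endothelial and 3.54 (1.97 to 6.91) in alveolar macrophage-like cells. Btg2, an antiproliferative p53 target, was not higher in epithelial (0.963; 0.883 to 1.05) or endothelial cells (0.835; 0.679 to 1.03) and was lower in myeloid cells (0.781; 0.722 to 0.845). By class the list median was 1.24 in AT2-like cells, 1.13 in alveolar fibroblast-like cells, 0.98 in alveolar macrophage-like cells, 0.89 in general capillary-like cells and -0.07 in non-classical monocyte-like cells, where Cdkn1a was at 453 and 445 CPM.

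Cebpb, which encodes a transcription factor of inflammation and myeloid differentiation, was among the named genes in monocyte-like cells at 314 and 5010 CPM, 15.9 times the control (12.3 to 20.99), and in alveolar fibroblast-like cells at 69.7 and 972 CPM. Dbp, an output gene of the circadian clock, was at 26.0 and 202 CPM in AT2-like cells, a ratio of 7.78 (5.09 to 12.4). Lrg1, a secreted glycoprotein, and Itih4, an acute phase protein, were lower in AT2-like cells, at 0.293 (0.258 to 0.332) and 0.371 (0.298 to 0.461). Eln, the elastin gene, was at 0.279 (0.211 to 0.368) in alveolar fibroblast-like cells, and the heat shock gene Hspa1a at 0.177. In alveolar macrophage-like cells the neutrophil attractant Cxcl2 was at 0.343 (0.285 to 0.411) and Hmgcs1, of cholesterol synthesis, at 0.264. In monocyte-like cells H2-Eb1, an antigen-presenting molecule, was 8.07 times higher (5.57 to 12.1), on 29 control UMIs. The FLASH ratio of H2-Eb1 to the same control library turned below 1 under other mitochondrial limits and doublet settings, so the size of the CONV ratio is uncertain. In the same class Isg15, an interferon-induced modifier, was at 0.281 and the linker histone gene Hist1h1c at 0.313. B-like cells had more S100a10 (2.07) and Pfn1 (1.87), which act at the membrane and on actin, and less H3f3b (0.546) and 1110001J03Rik (0.217).

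In T-like cells as a whole Dapl1 was 3.03 and Atp11b 2.98 times the control, and Endou and Arpp21 had 0 UMIs against 199 and 193, genes of the control-rich T-like clusters. Within the T-like cluster shared by all libraries Hivep2, a zinc finger regulator of T cell genes, was 4.42 times (2.07 to 10.9) and Atp11b, a phospholipid flippase, 2.36 times the control (1.68 to 3.37). Tubb2a, a tubulin, was at 0.281 and Ikzf2, the Helios factor, at 0.262. Ikzf2 also marks the T-like cluster that was 82.3% control. Ccr9, another gene of the control-rich clusters, had 41 control and 14 CONV UMIs in the shared cluster. Some such cells or their free RNA are therefore not excluded as a source of the Ikzf2 value.

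The lists of antigen presentation and interferon genes were lower in CONV epithelial and endothelial cells as a whole, and mixed elsewhere. The MHC class II list had a median of -0.68 (-0.79 to -0.61) in epithelial cells, -0.75 (-0.86 to -0.71) in myeloid cells and -2.12 (-2.68 to -1.85) in endothelial cells, with every measured member lower in each. In stromal cells it was higher, at 0.58 (0.38 to 1.01), with Cd74, the class II chaperone, at 205 and 306 CPM against 18460 CPM in control myeloid cells, a level so low that free RNA is not excluded. The myeloid value goes with the mix of classes: type 2 dendritic-like cells, which present antigen, were 52 of 232 control but 51 of 617 CONV myeloid cells. Within monocyte-like cells, 62 in the control, the list was higher, at 1.37 (1.28 to 1.60), with Cd74 at 2.59 (2.40 to 2.80). Its member H2-Eb1 carries the limit given above. The list and Cd74 were not recomputed in this class under those settings, so their stability is not known. Within alveolar macrophage-like cells the list was level at -0.04 (-0.13 to 0.29). Cd74 was at 0.592 (0.571 to 0.614) of the control in epithelial, 0.556 (0.544 to 0.568) in myeloid and 0.140 (0.108 to 0.180) in endothelial cells. The class I list was at -1.12 in endothelial, -0.42 in epithelial, -0.37 in myeloid and -0.30 in stromal cells, and B2m, the class I light chain, at 0.405 (0.366 to 0.447) in endothelial cells. The interferon-stimulated list was at -1.24 (-1.66 to -0.88) in endothelial, -0.65 (-0.83 to -0.31) in epithelial, -0.45 (-0.65 to -0.21) in stromal and -0.44 (-0.63 to -0.24) in myeloid cells. Isg20 was at 0.618 (0.480 to 0.796) in epithelial cells. Within AT2-like cells Isg20 was level at 1.01 (0.651 to 1.58), Bst2 at 1.03 and Ifi27l2a at 0.947. The epithelial Isg20 value may therefore follow the mix of classes. The most abundant member of the list, Ifitm3, did not follow, at 0.957 in epithelial, 2.55 in AT2-like and 1.13 in myeloid cells. Its level in AT2-like cells was 35.1 and 89.5 CPM, against 2170 CPM in control stromal cells, so free RNA is not excluded there. The same holds for Ifi27l2a in AT2-like cells, at 32.8 CPM against 874 CPM in control stromal cells. In endothelial cells Ifi27l2a was at 3.69 (2.11 to 6.80), and 19 of 93 of them in CONV but 0 of 91 in the control were lymphatic-like.

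Cytokine genes of myeloid cells were mostly lower in CONV, with a median of the inflammatory list of -0.45 (-0.55 to -0.33) and 19 of 22 members lower. Il1b, an early cytokine, was at 1478 and 1130 CPM, a ratio of 0.764 (0.713 to 0.820), Tnf at 0.721 (0.544 to 0.957; level at a mitochondrial limit of 5%) and Il6 at 0.575 (0.424 to 0.780), while Cxcl1, which draws neutrophils, was level at 0.991 (0.742 to 1.33). Tgfb1, the profibrotic cytokine, was at 139 and 438 CPM, a ratio of 3.15 (2.61 to 3.82), and the matrix list of myeloid cells had a median of 1.02 (0.55 to 1.36). The list was as high in lymphoid cells without the control-rich clusters, at 1.16 (0.80 to 1.81), which are not matrix makers, so free stromal RNA is not excluded as a source. Stromal cells did not share it: their matrix list was at -0.24 (-0.37 to -0.16), and this sign depends on how the stromal classes are weighted. The contractile genes Acta2, at 0.552 (0.515 to 0.591), and Tagln, at 0.657, mark the smooth muscle-like cells. Those were 29 of 185 control but 46 of 582 CONV stromal cells, so both ratios may follow the mix of classes. Endothelial Tgfb1 was 4.36 times the control (2.63 to 7.54), and the endothelial activation list was at 0.25 (-0.04 to 0.53). The lymphoid inflammatory list was at 0.85 (0.63 to 0.99) with all cells and at 0.09 (-0.12 to 0.32) without the control-rich clusters.

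Epithelial identity was largely level in CONV. The surfactant list had a median of 0.01 (-0.05 to 0.03), and Sftpc, the AT2 surfactant gene, a ratio of 0.968, whose sign turns with the mitochondrial limit. Scgb1a1, the club cell secretoglobin, was at 0.767. The Krt8-high transitional list was at -0.25 (-0.52 to -0.07), with Krt18 at 0.673 and Krt8, its keratin partner, at 0.838. Immediate early genes were at -0.49 (-0.54 to -0.39) in epithelial and -0.32 in stromal cells, with Fos at 0.795 and Jun at 0.720 in epithelial cells. The NRF2 list was at 0.13, the senescence list at 0.38 in epithelial and 0.47 in myeloid cells, and the mitochondrially encoded list at 0.01 in epithelial cells. The S phase list was at -2.58 and the G2/M list at -4.18 in lymphoid cells, but at -0.26 and 0.08 without the control-rich clusters.

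After FLASH irradiation the p53 list was also higher in every non-lymphoid compartment, measured against the same control library as CONV. Cdkn1a was at 710 CPM in stromal cells, 5.72 times the control (4.54 to 7.28), and its ratio was 3.59 (3.05 to 4.24) in epithelial, 2.67 (2.28 to 3.13) in endothelial and 2.29 (2.04 to 2.56) in myeloid cells. In alveolar fibroblast-like cells it was at 769 CPM, 17.7 times the control (9.44 to 37.3), in AT2-like cells 5.91 times (4.66 to 7.59) and in general capillary-like cells 3.13 times (2.55 to 3.86). Ccng1 was 9.64 times higher in AT2-like cells (5.69 to 17.6). The p53 list had medians of 1.497 (1.16 to 1.67) in endothelial, 0.98 (0.83 to 1.21) in epithelial, 0.91 (0.70 to 1.15) in stromal and 0.74 (0.49 to 0.97) in myeloid cells, each at percentile 100, and of 0.51 (0.26 to 0.74) in lymphoid cells without the control-rich clusters (-0.01 with them). Rps27l was at 3.12 in endothelial, 1.94 in epithelial and 2.01 in stromal cells, Phlda3 at 3.01 (2.27 to 4.01) in endothelial and 3.54 in alveolar macrophage-like cells. Btg2 was lower in endothelial (0.593; 0.465 to 0.752) and myeloid cells (0.785; 0.723 to 0.853), and in monocyte-like cells the list median was 0.09 and Cdkn1a at 0.916.

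**Figure D3:**
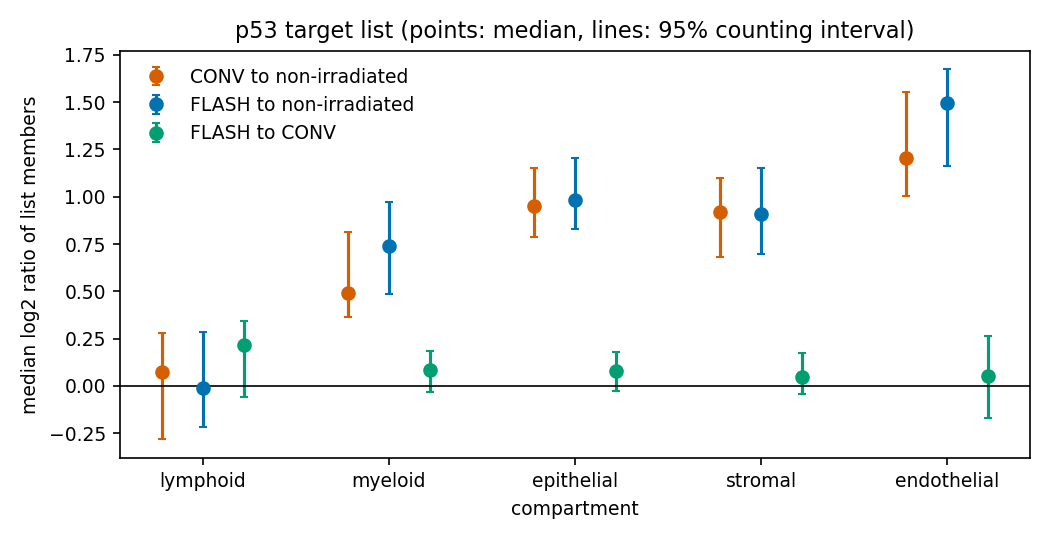
Median log2 ratio of the p53 target list (vertical axis) per compartment for CONV and FLASH against the control and FLASH against CONV, with 95% counting intervals as error bars. Epithelial values are 0.95, 0.98 and 0.08.

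Other named genes of FLASH against control overlap with those of CONV, but both comparisons share the same control library, so a departure of that library would give the overlap as well. Cebpb was at 3537 CPM in monocyte-like cells, 11.2 times the control (8.67 to 14.8), and 9.70 times (5.84 to 17.3) in alveolar fibroblast-like cells. Dbp was 9.77 times higher in AT2-like cells (6.38 to 15.7). Itih4 was at 0.318 (0.244 to 0.412) and Tmem213, a membrane protein gene, at 4 against 33 UMIs in AT2-like cells. Eln was at 0.462 (0.350 to 0.608) and Mmp3, a matrix protease, at 0.0775 (4 against 38 UMIs) in alveolar fibroblast-like cells, although Mmp3 marks a neighbouring unnamed stromal cluster. Alveolar macrophage-like cells had Cxcl2 at 0.407 (0.340 to 0.485) and the histone variant H2afv at 0.293. In monocyte-like cells Isg15 was at 0.314, Ly6i, a surface antigen of monocytes, at 0.215, and H2-Eb1 at 4.75, a value that turns below 1 under 4 other settings. B-like cells had S100a10 at 2.13, Pfn1 at 1.98, the glycolipid remodelling gene Pgap1 at 0.147 and Dnajb1, a heat shock cochaperone, at 0 against 32 UMIs.

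In T-like cells as a whole Igfbp4 was 3.49 and Atp11b 3.32 times the control, with Dntt at 0 against 455 UMIs and Endou at 0 against 199. Within the shared T-like cluster Igfbp4, which binds insulin-like growth factors, was at 2.21 (1.72 to 2.86), Lgals1, a galectin, at 2.27 (1.69 to 3.08), Ikzf2 at 0.154 and Tubb2a at 0.314. The limit given for Ikzf2 in CONV holds here as well.

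MHC class II genes in FLASH were at -0.68 in epithelial, -1.12 (-1.18 to -1.07) in myeloid and -1.93 in endothelial cells, with Cd74 at 0.601 (0.578 to 0.625), 0.415 (0.405 to 0.425) and 0.210 (0.168 to 0.261). In stromal cells, unlike in CONV, Cd74 was lower at 0.614 (0.473 to 0.795), with H2-Ab1 at 0.707 (0.440 to 1.13), H2-Aa at 0.904 and H2-Eb1 at 1.33 (0.676 to 2.69). As in CONV, the myeloid value goes with fewer dendritic-like cells (40 of 610): within monocyte-like cells the list was higher at 0.69 (0.59 to 1.02), with its member H2-Eb1 unstable between settings, and within alveolar macrophage-like cells lower at -0.49 (-0.72 to -0.14). The class II list was not recomputed within these classes under the other settings. In lymphoid cells the class II list was at 0.32 with all cells and at -0.89 without the control-rich clusters, so its sign follows the mix of cells. The lymphoid values of CONV were -0.14 and -1.40 (-1.46 to -1.21), and without these clusters FLASH to CONV was at 0.33 (0.26 to 0.45). Class I genes were at -0.91 in endothelial, -0.41 in epithelial, -0.48 in myeloid and -0.19 in stromal cells. The interferon list was at -0.72 in epithelial, -0.51 in myeloid and -0.46 in stromal cells, but at -0.26 (-0.85 to 0.01) in endothelial cells, where 14 of 23 members were lower.

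The myeloid inflammatory list was at -0.22 (-0.34 to -0.07) in FLASH. Il1b was at 1180 CPM, a ratio of 0.798 (0.743 to 0.859), Tnf at 0.765 (0.571 to 1.03), Cxcl1 at 233 CPM and 2.89 (2.24 to 3.76), and Il6 at 1.43 (1.10 to 1.87), which does not hold when each cell is weighted equally. Tgfb1 was at 357 CPM, a ratio of 2.57 (2.11 to 3.14), and the myeloid matrix list at 1.45 (1.01 to 1.72), beside 1.30 (0.83 to 1.88) in lymphoid cells without the control-rich clusters. In stromal cells the matrix list was at -0.21, with Acta2 at 0.574 and Tagln at 0.557, and the sign of the list again depends on the weighting of classes. Smooth muscle-like cells, which the 2 genes mark, were 1.70% of control and 1.46% of FLASH cells. All stromal cells were 10.9% and 21.6%, so the ratios of the 2 genes may again follow the mix of classes. Sftpc was at 0.966 and Scgb1a1 at 0.744 of the control in epithelial cells, with the surfactant list at -0.05 (-0.12 to -0.04), and the signs of Sftpc and of the list turn at a mitochondrial limit of 5%. The Krt8-high list was at 0.07 (-0.05 to 0.24) and immediate early genes at -0.22 (-0.27 to -0.09) in epithelial cells. The NRF2 list was at 0.28 (0.16 to 0.40), the senescence list at 0.55 and the S phase list at -0.66 in myeloid cells, endothelial activation at 0.14 in endothelial cells and mitochondrially encoded genes at 0.00 in epithelial cells. The G2/M list was at -1.11 in epithelial and -0.45 in myeloid cells, and at -4.23 in lymphoid cells, or 0.13 without the control-rich clusters. For the S phase and G2/M values outside the lymphoid cells, free RNA of the dividing control-only cells is not excluded. Of the non-lymphoid cells, 14 of 706 in the control but 0 of 1715 in FLASH held at least 2 UMIs of Rag1, Rag2, Dntt and Ptcra.

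**Figure D4:**
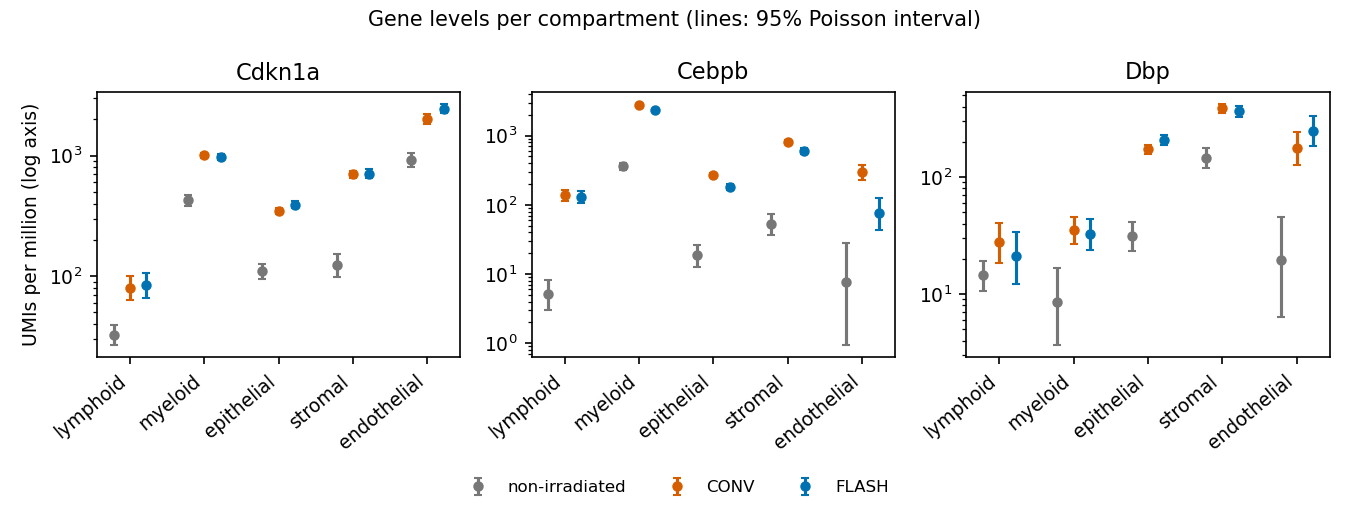
Levels of Cdkn1a, Cebpb and Dbp (CPM, log axis) per compartment in the control, CONV and FLASH libraries, with 95% Poisson intervals as error bars. Stromal Cdkn1a is at 124, 699 and 710 CPM.

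FLASH and CONV were close for p53 targets. Cdkn1a had a FLASH to CONV ratio of 1.02 in stromal, 0.970 in myeloid, 1.13 (1.03 to 1.24) in epithelial and 1.22 (1.07 to 1.39) in endothelial cells, the last led by general capillary-like cells at 1.69 (1.39 to 2.05). The p53 list was at 0.05 (-0.17 to 0.27) in endothelial, 0.08 (-0.03 to 0.18) in epithelial, 0.05 (-0.04 to 0.17) in stromal and 0.08 (-0.03 to 0.18) in myeloid cells. General capillary-like cells differed more, at 0.28, and between 0.21 and 0.42 under the other settings. Their medians against the control were 1.66 in FLASH and 0.89 in CONV. The class held 74 control, 59 CONV and 82 FLASH cells. It also held all endothelial UMIs of Vwf, one of the fixed markers of venous endothelium, at 1124, 2066 and 1458 CPM in these libraries. The mix of cells within the class may therefore contribute to its Cdkn1a and p53 values. The other classes measured lay between -0.08 (T-like) and 0.21 (NK-like). Shares differed little: B-like cells by 2.10 points (0.847 to 3.38), NK-like cells by 1.62 points and general capillary-like cells by 1.17 points (0.178 to 2.19) were more frequent in FLASH, AT2-like cells by -2.23 points (-4.32 to -0.124) less. Cycling differed by 0.697 points (-1.25 to 2.66), but dividing myeloid cells by the narrow list were 12 of 609 (1.97%) in FLASH against 27 of 617 (4.38%) in CONV, and the myeloid G2/M list was at -0.78 (-0.91 to -0.50) with 27 of 29 members lower. The CONV level behind this is unstable, as its median against the control, 0.13 (0.03 to 0.50), turns below 0 under 5 other settings.

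Cebpb was lower in FLASH than in CONV, at 0.706 (0.663 to 0.752) in monocyte-like cells, 0.696 (0.589 to 0.819) in alveolar fibroblast-like cells, 0.741 (0.666 to 0.822) in stromal and 0.255 (0.135 to 0.452) in endothelial cells. Monocyte-like cells of FLASH had less H2-Ab1 (0.553; 0.502 to 0.608) and H2-Aa (0.575; 0.522 to 0.634), the class II chains, and more Gstp1 (2.28), a detoxifying enzyme, and Vmp1 (1.97), of autophagy. The class II list was at -0.40 (-0.45 to -0.31) in myeloid cells. Endothelial cells went the other way, with the interferon list at 0.53 (0.16 to 1.01), class I at 0.26 (0.02 to 0.52) and B2m at 1.40 (1.25 to 1.58).

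Immediate early genes were higher in FLASH than in CONV, at 0.24 (0.20 to 0.31) in epithelial, 0.20 (0.13 to 0.27) in myeloid and 0.12 (0.05 to 0.21) in stromal cells. In AT2-like cells the named genes were Socs3, a brake on cytokine signalling, at 1.91 (1.49 to 2.47), Egr1, an immediate early factor, at 1.58 (1.38 to 1.82), the ubiquitin ligase gene Smurf1 at 0.287 and the magnesium transporter gene Mmgt1 at 0.276. In epithelial cells as a whole the Krt8-high list was at 0.34 (0.24 to 0.46) with 14 of 14 members higher, Krt8 at 1.30 (1.18 to 1.42) and Krt18 at 1.24 (1.13 to 1.36). Alveolar type 1-like cells, marked by the list member Krt7, were 32 of 590 CONV and 43 of 505 FLASH epithelial cells. The mix of classes may therefore contribute, and the list was not measured by class. Alveolar fibroblast-like cells had more Cyr61, a matricellular target of YAP, at 2.23 (1.87 to 2.66), and Sln, a calcium pump regulator, with 30 UMIs against 1, and less of the chromatin regulator Ankrd11 (0.324) and the vesicle fusion gene Snap23 (0.263). The class of alveolar macrophage-like cells had more Fabp5, a fatty acid carrier, at 1.75 (1.45 to 2.12), and less Rab35 (0.280) and Sp1 (0.332). B-like cells had Arpc5l at 2.09, Rwdd1 at 2.59, Lamb3 at 0.399 and Eif4g2 at 0.459. T-like cells had Marc2 at 2.08, Lypla2 at 0.293, Malat1 at 1.28 and Banf1 at 0.436. Within the shared T-like cluster Dnajb9, a chaperone of the endoplasmic reticulum, was at 2.23 (1.25 to 4.07), Malat1, a nuclear RNA, at 1.26 (1.23 to 1.30), Banf1, a DNA-binding lamina protein, at 0.390 and Pdap1 at 0.359.

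Myeloid Cxcl1 was higher in FLASH than in CONV at 2.91 (2.37 to 3.59) and Il6 at 2.49 (1.93 to 3.25), but Il6 was at 1.31 (0.885 to 1.93) without a cluster of 28 cells marked by Saa3 and Prg4, of which 18 were FLASH. Cxcl1 stayed at 3.09 (2.31 to 4.19) without it. Il1b was level at 1.05 (0.977 to 1.12), Tnf at 1.06 and Tgfb1 lower at 0.816 (0.726 to 0.916). The inflammatory list was at 0.12 (0.05 to 0.20), with Cxcl2 at 1.31 (1.24 to 1.39). Sftpc was level at 0.998 and Scgb1a1 at 0.969 in epithelial cells, the latter turning above 1 with at least 500 genes per cell. Sftpc reads were also found outside the epithelium, where free RNA is their usual source, and their level differed between libraries: stromal cells held 935, 3048 and 2259 CPM in control, CONV and FLASH, and the surfactant list of stromal cells was at 1.29 in CONV and 0.71 in FLASH against the control. Scgb1a1 in stromal cells was at 5182, 7372 and 7294 CPM.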

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

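Haemoglobin transcripts were at 694 CPM in the kept CONV cells and at 1235 CPM in the kept FLASH cells, against 40.0 CPM in the control. Over all barcodes before filtering they were 0.133% of UMIs in the control, 0.280% in CONV and 1.06% in FLASH. Most haemoglobin UMIs therefore lay in removed barcodes. Before filtering the ratios to the control were smaller, while the differences in level from the control were larger. By compartment Hbb-bs, a beta globin gene, was at 17.5, 484 and 132 CPM in control, CONV and FLASH epithelial cells, and at 20.1, 82.4 and 2132 CPM in lymphoid cells. In CONV 5 cells with at least 100 haemoglobin UMIs held 81.9% of them, and in FLASH 6 such cells held 79.8%, a split chosen after the library values were seen. The remainder was at 125 CPM in CONV and 249 CPM in FLASH, and at least 1 haemoglobin UMI was found in 12.7% of control, 26.8% of CONV and 39.0% of FLASH cells.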

How the results depend on the processing

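Shares, medians and ratios were recomputed under other settings, of which the removal of 1-library or control-rich clusters, the shares among non-lymphoid cells, the narrow G2/M list, the limit of 10% of the highest compartment, the list without Cdkn1a and random seed 1 were chosen only after the results had been seen. No paired analysis was possible because each group is 1 library and no sample is shared between groups. Under the settings chosen beforehand 503 of 597 class shares and 126 of 150 compartment shares stayed within the main interval, and 94 and 24 moved. Of 27 cycling shares 15 stayed and 12 moved. A value is called turned when its main interval excluded 0 and the new value lay outside that interval with the other sign. Of 2481 list medians 2230 stayed, 231 moved and 20 turned, and 2286 kept their sign. Of 1316 gene ratios 1166 stayed, 139 moved and 11 turned, and 1290 kept their sign. Under the settings chosen afterwards 54 of 60 class shares, 34 of 57 compartment shares, 4 of 9 cycling shares, 807 of 857 list medians and 175 of 188 gene ratios stayed, and 11 medians and 4 ratios turned, with the sign kept by 819 medians and 184 ratios. The compartment shares, cycling shares and compartment p53 medians that left their main interval, and every value that turned, are given one setting at a time, and the cause was not tested.

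With a mitochondrial limit of 5% epithelial cells were 7.19% of control, 16.4% of CONV and 15.5% of FLASH cells, lymphoid cells 61.1%, 24.4% and 26.5%, CONV myeloid cells 27.8%, and stromal cells 27.0% of CONV and 23.8% of FLASH. Signs turned for the FLASH to control medians of S phase (0.0000942) and surfactant (0.25) in epithelial cells, the CONV median of G2/M in myeloid cells (-0.86), the log2 ratios of Sftpc in epithelial cells (0.15 in CONV, 0.25 in FLASH), H2-Eb1 in FLASH monocyte-like cells (-0.46) and Tnf in CONV myeloid cells (0.000127). With a limit of 20% control lymphoid cells were 50.3% and H2-Eb1 was at -0.16. With at least 500 genes per cell epithelial cells were 10.0% of control and 22.3% of CONV, lymphoid cells 50.8% of control and 21.9% of FLASH, and epithelial Scgb1a1 was at 0.31 for FLASH to CONV.

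Without doublet removal the CONV matrix median in endothelial cells was 0.0069, the FLASH to CONV surfactant median in endothelial cells 0.11, the CONV G2/M median in myeloid cells -0.44, H2-Eb1 in FLASH monocyte-like cells -0.33 and Sftpc for FLASH to CONV in endothelial cells 0.21. With the automatic Scrublet threshold control lymphoid cells were 50.5%, the CONV Krt8-high median in endothelial cells 0.27, the FLASH to CONV surfactant median there 0.041, Sftpc 0.21, the CONV G2/M median in myeloid cells -1.04 and H2-Eb1 in FLASH monocyte-like cells -0.39.

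At resolution 2 epithelial cells were 9.97% of control and 22.7% of CONV. When each cell was assigned by its own marker score, lymphoid cells were 54.7%, 16.9% and 18.2% and endothelial cells 4.77% of CONV. With the libraries clustered separately endothelial cells were 6.79% and stromal cells 19.9% of FLASH. With cells thinned to 1000 UMIs control lymphoid cells were 47.2%, and with random seed 1 they were 50.7%. Control lymphoid cells stayed above the lymphoid share of both irradiated libraries throughout.

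Cycling cells with at least 1 UMI were 60.6% of control, 40.9% of CONV and 43.1% of FLASH, and with at least 3 UMIs 20.9%, 5.19% and 4.50%. Without thinning they were 69.3%, 38.0% and 29.9%, and with thinning to 500 UMIs 19.9%, 5.23% and 5.02%. With the narrow G2/M list they were 12.2%, 1.26% and 0.713%. Control cycling was 22.7% without the 1-library clusters and 21.4% without the control-rich clusters.

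With a mean over cells the CONV matrix median in endothelial cells was 0.20, the CONV G2/M median in myeloid cells -0.29, the FLASH MHC class II median in lymphoid cells -0.18 and Il6 in FLASH myeloid cells -0.084. With a pseudocount of 10 CPM the p53 median was 0.69 in CONV and 0.76 in FLASH epithelial cells and 0.69 in FLASH stromal cells. With members of 1 UMI or more it was 0.33 in CONV lymphoid cells. With classes weighted equally the p53 median was 0.70 in CONV and 0.66 in FLASH epithelial cells, -0.14 for FLASH to CONV, and 1.68 in FLASH endothelial cells. Under the same weighting the stromal matrix median was 0.086 in CONV and 0.16 in FLASH, the FLASH stromal medians of immediate early genes 0.028 and of the Krt8-high list 0.20, the CONV G2/M median in myeloid cells -0.87, and in lymphoid cells NRF2 was at 0.21 in CONV and MHC class II at -0.36 in FLASH and -0.027 for FLASH to CONV.

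Without the 1-library clusters the control was 6.57% endothelial, 14.3% epithelial, 49.0% lymphoid, 16.8% myeloid and 13.4% stromal. In lymphoid cells the p53 median was 0.31 in CONV and 0.40 in FLASH, immediate early genes -0.15 in CONV and MHC class II -0.55 in FLASH.

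Without the control-rich clusters the control was 7.45% endothelial, 16.2% epithelial, 42.2% lymphoid, 19.0% myeloid and 15.1% stromal. In lymphoid cells the p53 median was 0.50 in CONV and 0.51 in FLASH, G2/M 0.080 and 0.13, immediate early genes -0.15 and -0.059, NRF2 0.17 in CONV and MHC class II -0.89 in FLASH. Lymphoid Mki67 turned to a log2 ratio of 1.58 in CONV and 1.87 in FLASH, on 4, 9 and 9 UMIs in control, CONV and FLASH, and Top2a to 0.086 and 0.37.

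Among non-lymphoid cells the control, CONV and FLASH shares were 12.9%, 4.94% and 6.59% endothelial, 28.0%, 31.3% and 29.4% epithelial, 32.9%, 32.8% and 35.6% myeloid, and 26.2%, 30.9% and 28.4% stromal. With members at 10% or more of their highest compartment, S phase in epithelial cells was at 0.12 in CONV and 0.11 in FLASH, and the matrix list at -0.29 in CONV.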

Other observations

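Several genes outside the fixed ones differed between the libraries and were chosen after their values were seen, as members of the lists. Gdf15, a stress cytokine induced by p53, was at 4.22, 33.7 and 42.6 CPM in control, CONV and FLASH epithelial cells, 8.00 times the control in CONV (3.74 to 20.4) and 10.1 times in FLASH (4.70 to 25.9). Ccl5, which draws T cells, was at 1533, 2756 and 5226 CPM in lymphoid cells, values that move with the NK-like share and the control-only cells. Within NK-like cells its FLASH to CONV ratio was 1.37 (1.30 to 1.44), and within the shared T-like cluster 2.24 (1.84 to 2.72). Mt1, a metallothionein, was at 1278, 1325 and 2150 CPM in myeloid cells, a FLASH to CONV ratio of 1.62 (1.54 to 1.72). Vcam1, an adhesion molecule for leukocytes, was at 448, 766 and 1192 CPM in endothelial cells, with 1.71 (1.34 to 2.19) in CONV and 2.66 (2.12 to 3.35) in FLASH against the control.

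Lymphatic endothelial-like cells were 0 of 1705 in the control, which allows a share of up to 0.176%, and 0.796% of CONV and 0.577% of FLASH cells. Dusp1, a phosphatase of the immediate early response, was 1.61 times higher in FLASH than in CONV stromal cells (1.46 to 1.77).

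Of the explanations weighed here, a shift of every control cell, loss of cells after irradiation, scaling of the libraries and dissociation stress were chosen only after the results had been seen.

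The clusters of 99 and 221 control cells may be thymocytes taken along with the lung. Of 10 further thymocyte genes, 7 were at 2 or more times their level in control cells of the shared T-like cluster, the least that the prediction asked for. Among them were Arpp21 (369 against 0 CPM) and Cd24a (493 against 45.2 CPM), but not Satb1 or Cd1d1. Cplx1 had 0 UMIs in these cells and could not be judged. Arpp21 was also selected by the rule for named genes in T-like cells, so it is not independent of that result. A shift large enough to set control cells of every kind apart was not seen, since 0 of the 23 other clusters of at least 20 cells held 95% or more of their cells from 1 library. A smaller shift of every control cell would not form such clusters, so this count cannot exclude it. Loss of such cells after irradiation could not be told apart from a difference in dissection: cells with at least 2 UMIs of Rag1, Rag2, Dntt and Ptcra were 0% of either irradiated library (0 of 2388 and 0 of 2253, limits of 0.126% and 0.133%) and 19.9% of the control, where 14 of 706 non-lymphoid cells (1.98%) also passed this limit.

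The higher p53 list in both irradiated libraries is unlikely to come from scaling, since the lower of the stromal medians was 0.99 after scaling by the median ratio. Free RNA shared by all cells could not be excluded. The lower stromal median was 0.94 with members at 10% or more of their highest compartment, so members that are low in stromal cells do not account for it. Members found in every compartment, such as Rps27l, pass this limit whether or not free RNA adds to them. Dissociation stress may contribute and could not be excluded: the highest median of the immediate early list in irradiated epithelial and stromal cells was -0.11, against 0.03 with classes weighted equally. A response of the tissue to irradiation remains possible, but 1 library per group cannot separate it from differences between animals.

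Higher Dbp in both irradiated libraries might reflect another phase of the circadian clock at sampling. In non-lymphoid cells the clock genes in phase with Dbp exceeded those of the opposite phase by a log2 difference of 1.91 in CONV and 1.58 in FLASH, with Per3 at 2.70 and 2.40 times, Tef at 2.37 and 2.59 times and Arntl at 0.434 and 0.401 times the control. Not every gene followed: of the opposite phase Cry1 was at 1.05 and 1.43 times, and Clock at 0.896 times in FLASH (0.681 to 1.18). A change in AT2-like cells alone does not account for it, since the lowest bound of the Dbp ratio in stromal and myeloid cells was 1.78. The hour of sampling was not given in the sources used here, so an effect of irradiation on the clock stays open.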
